A study of Saccharomyces cerevisiae with 4 samples.

How the data were processed

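ChIP-chip was used to map where 2 proteins of the yeast nuclear pore, Nup157p and Nup170p, sit on the genome of Saccharomyces cerevisiae. Each protein carried a 9xMyc tag and was pulled down with an anti-Myc antibody. Per the labels, cells grew in rich medium at 30 °C to an optical density of 1, were cross-linked with 1% formaldehyde for 1 h, and had their chromatin sheared to about 400 bp. There were 4 libraries, 1 in each group: Nup157 in a strain labelled wild type, Nup170 in a strain labelled wild type, and Nup170 in strains labelled sir4∆ and yku70∆. ChIP DNA was labelled with Cy5 and whole cell extract DNA of the same strain with Cy3. Each file holds 2 hybridisations of its library, and nothing in the labels says that these came from separate cultures, so they were treated as repeat measurements of 1 library.

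The deposited intensity columns give the foreground and local background brightness of each spot in both channels, with Agilent Feature Extraction named in the labels and no version stated. The authors also gave normalised intensity values, and the values show how these were made: background and a further constant were subtracted, and each channel was scaled so that both had the same median. The deposited log2 columns hold the base 2 logarithm of normalised ChIP over normalised whole cell extract signal, per hybridisation and combined, which was checked on the values. The authors' combined log2 ratio weights the hybridisations, with the first given 49.2%, 53.1%, 97.7% and 48.7% in the Nup157, Nup170 wild-type, sir4∆-labelled and yku70∆-labelled libraries. The series matrix holds that combined ratio. Per the file headers, further columns hold a p-value for each probe, which was not used here. Per the file headers, there is also a score for each hybridisation, which was not used here. The deposited 0 or 1 marks, a unit of another kind (other), say whether a spot is to be left out and whether a probe lies in a bound region. The genome build is not given in the sources used here. Gene positions in the files differ from release R64 by up to -360 bp on chromosome 11 and -305 bp on chromosome 10, so all positions given here are those of the files.

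Of 41775 probes, 295 on the mitochondrial genome were left out and 41480 remained on 16 chromosomes, with a median spacing of 257 bp. Spots marked for exclusion were removed. The value of a probe was the mean over both hybridisations of log2(ChIP / whole cell extract), each hybridisation centred on its median. Names came from the RefSeq table, which matched 5639 of the 5659 genes annotated in the files. A gene value was the mean over probes in the open reading frame (ORF) or within 500 bp upstream, with at least 2 probes, and 5567 genes had one. Differences between libraries were taken probe by probe, over probes measured in both. Genes that the labels give as deleted were left out of gene values.

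Enriched regions were called on values smoothed as the mean of all probes within 500 bp. A probe counted as enriched at 3 or more robust SDs above the median, with the SD taken from the lower side of the smoothed values (median minus the 16th percentile). A region needed at least 2 enriched probes with gaps of at most 1000 bp. Subtelomeres were defined as the outermost 20 kb of each of 32 chromosome arms, measured from the first or last probe, and log2 ratios were also summarised in steps of 5 kb out to 50 kb. Medians carry a 95% order-statistic interval over probes or genes, and shares an exact binomial (Clopper-Pearson) interval. These intervals cover the spread between probes or genes only, not that between cultures. They treat probes as independent, although probes lay a median of 257 bp apart and fragments were about 400 bp long. The intervals may therefore be too narrow. Medians were set beside 10000 random sets: runs of neighbouring probes for subtelomeres, and gene lists of equal size matched on whole cell extract signal for genes. A probe was called near blank when its whole cell extract foreground was not above the mean of 660 blank spots plus 2.6 SDs in 1 or both hybridisations. With 1 library in each group, no p-value was computed and the number of arrays limits the precision of every comparison.

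The regions, the gene lists, the comparisons with the Nup170 wild-type library and the rule for naming genes were chosen before the data were examined. The lists were cytosolic ribosomal proteins, mitochondrial ribosomal proteins, ribosome biogenesis, glycolysis, translation factors, histones, inducible genes known from the nuclear periphery, the subtelomeric families COS, PAU, YRF1 and FLO, silent mating loci, a-specific genes, haploid-specific genes, the proteasome, meiosis, the nuclear pore, silencing factors and amino acid biosynthesis. The rule names the 10 genes with the highest gene value in each library, and the 10 highest and 10 lowest in each difference, with at least 3 probes, all of the same sign, passing over a gene that shares a probe with one already named. It also names the 2 highest and 2 lowest members of each list described, and the genes used to check the strain labels. Probe sequences were not used here, so probes that match several places could not be recognised and were not left out. The label check compared the whole cell extract signal of probes inside SIR4, YKU70 and marker genes with the median of those of the other 3 libraries that had a signal above 0 at the probe. For LYS2 these were, at most probes, the other 2 Nup170 libraries alone. MET17, HMRA1 and the alpha-specific genes were added to it after seeing the data.

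The steps were tested on simulated data with the real probe positions and independent normal noise of each library's lower-side SD. Noise shared by neighbouring probes and the spread between hybridisations were not simulated, so recovery in the real data may be lower. For Nup157 the threshold in the real data was 1.08, above each planted size. Noise alone gave 21 regions with the spread of the Nup157 library and 16 with that of each Nup170 library. Planted regions of 0.5 on the log2 scale were recovered in 10% of cases for the Nup157 library and in 76%, 90% and 92% for the Nup170 libraries labelled wild type, sir4∆ and yku70∆. At 1.0 the shares were 59% for Nup157 and 100% for each Nup170 library. A shift of 0.1 was recovered in all of 200 simulated lists of 135 genes for every library, and shorter lists were not simulated. Of unshifted lists, 6.0%, 7.5%, 4.5% and 6.0% fell outside the 95% range for Nup157 and the Nup170 libraries in the same order.

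Alternatives covered the signal (normexp background correction with an offset of 50, the authors' combined ratio), centring, scaling, probe filters, an intensity trend, thresholds, smoothing, the width of the subtelomere and the probes taken for a gene. Of the 26 settings, 23 were set in advance and 3 were added after seeing the data: each hybridisation alone, and left chromosome ends counted from coordinate 1. The outermost 5 kb was carried through these settings as an added result. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and in R 4.3.3 with limma 3.58.1 for normexp.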

Results

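Binding of 2 related nuclear pore proteins was measured across the genome of budding yeast as the log2 ratio of ChIP over whole cell extract DNA. Nup157p and Nup170p are paralogous scaffold proteins of the inner ring of the pore. The 4 groups, each of 1 library with no replicate culture, were Nup157 in wild type, Nup170 in wild type, Nup170 in a strain labelled sir4∆ and Nup170 in a strain labelled yku70∆. SIR4 encodes a silencing protein of telomeres and silent mating loci, and YKU70 a subunit of the Ku complex that binds chromosome ends. Of 41480 nuclear probes, 41409, 41423, 41425 and 41430 were used in these libraries, in that order. Between the 2 hybridisations of a library, Pearson's r across probes, which are not independent replicates, was 0.57 for Nup157, 0.68 for Nup170 in wild type, 0.63 for the library labelled sir4∆ and 0.70 for the library labelled yku70∆. The lower-side SD of the log2 ratios was 0.50 for Nup157 and 0.22, 0.19 and 0.18 for the Nup170 libraries. No untagged control was analysed here, so signal that a strain without the tag would give is unknown.

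In wild type, Nup170p gave high ratios over genes of the cytosolic ribosome. Genes called highest or lowest in a library or difference are those left by a filter: at least 3 probes, all on the same side of 0, and no probe shared with a gene already named. Some genes with higher values, such as PDC1, TEF1 and RPL3, did not pass it. The 10 highest genes that passed held 7 for ribosomal proteins: RPL8A (YHL033C, chromosome 8, probes from 35578 to 36287) at 1.16, RPL7A (YGL076C, chromosome 7, 364318 to 366503) at 1.10, RPL2B at 1.06, RPL28 at 1.06, RPS14B at 0.98, RPL13B at 0.96 and RPS4A at 0.95. The others were TDH3, a glycolytic dehydrogenase gene (YGR192C, chromosome 7, 883267 to 884087), at 1.15, TEF2, for translation elongation factor EF-1 alpha, at 0.96, and CTR2, a vacuolar copper transporter gene, at 0.91. Of 135 measured ribosomal protein genes, 133 lay above 0, with a median log2 ratio of 0.57 (95% interval 0.53 to 0.61), where random lists gave -0.060 to -0.017. The lowest members were RPP2B at -0.019 and RPS28A at -0.011.

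Other growth genes followed in the same library. Glycolysis had 17 of 18 genes above 0 and a median of 0.49 (0.23 to 0.81), from PDC1, for pyruvate decarboxylase, at 1.10 down to GPM1 at 0.010 and GLK1 at -0.032. Translation factors had 13 of 14 genes above 0 and a median of 0.44 (0.068 to 0.96), with TEF1 at 1.05 and YEF3 at 0.97 highest and CAM1 at -0.13 and TIF1 at 0.0050 lowest. Genes of ribosome biogenesis had a median of 0.070 (0.020 to 0.12) with 41 of 60 above 0, DBP2 at 0.38 and NOG2 at 0.37 being highest and ENP1 at -0.28 and NOP15 at -0.16 lowest. Genes of mitochondrial ribosomal proteins lay on the other side, with 54 of 66 below 0 and a median of -0.10 (-0.12 to -0.064), from MRP2 at -0.68 and RSM18 at -0.36 to RSM26 at 0.22 and MRP13 at 0.29. Meiosis genes, which are silent in growing cells, lay below 0 in 21 of 22 cases with a median of -0.058 (-0.11 to -0.035), inside the range of random lists (-0.090 to 0.017), from MEI4 at -0.31 to MER1 at 0.068. With upstream probes alone the glycolysis median turned to -0.31 and that of ribosome biogenesis to -0.14, while ribosomal protein genes kept 0.47. With the highest probe of each gene, the medians of mitochondrial ribosomal protein and meiosis genes turned to 0.11 and 0.17.

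Distances to a chromosome end were counted from its first or last probe, which can lie inside it. Regions counted as within 5 kb thus began at 5832 on chromosome 2 and at 6866 on chromosome 14. Chromosome ends carried Nup170p signal in wild type within the outermost 5 kb. There the median log2 ratio was 0.20 (0.15 to 0.26) over 354 probes, and 29 of 32 arms lay above 0. From 5 to 10 kb it was already -0.012 (-0.041 to 0.017), and over the whole 20 kb the median was 0.0042 (-0.011 to 0.016). YFR057W, the last gene on the right arm of chromosome 6 (probes from 268528 to 269339), stood at 0.74. The subtelomeric families COS and PAU, whose members are near identical, had medians of 0.32 over 6 measured genes and 0.18 over 8, led by COS12 at 0.46 and PAU19 at 0.84, with COS9 at -0.041 and PAU23 at -0.0083 lowest. None of the 8 YRF1 genes, copies of a helicase in telomeric Y' elements, was measured as a gene. In all, 351 enriched regions were called at a threshold of 0.41 (1.33-fold), of which 111 held a ribosomal protein gene and 22 lay within 5 kb of an end. Their number ranged from 194 without smoothing to 661 at a threshold of 2 SDs. Of the 15 regions with the highest maximum of the smoothed log2 ratio, a ranking looked at after seeing the data, 11 lay within 5 kb of an end and none held a ribosomal protein gene. The highest lay at URA3, where all 4 probes were at blank level in the whole cell extract, so its ratio cannot be read; next came regions at YER188C-A, with 4.42, and PAU19, with 4.13.

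**Figure D1:**
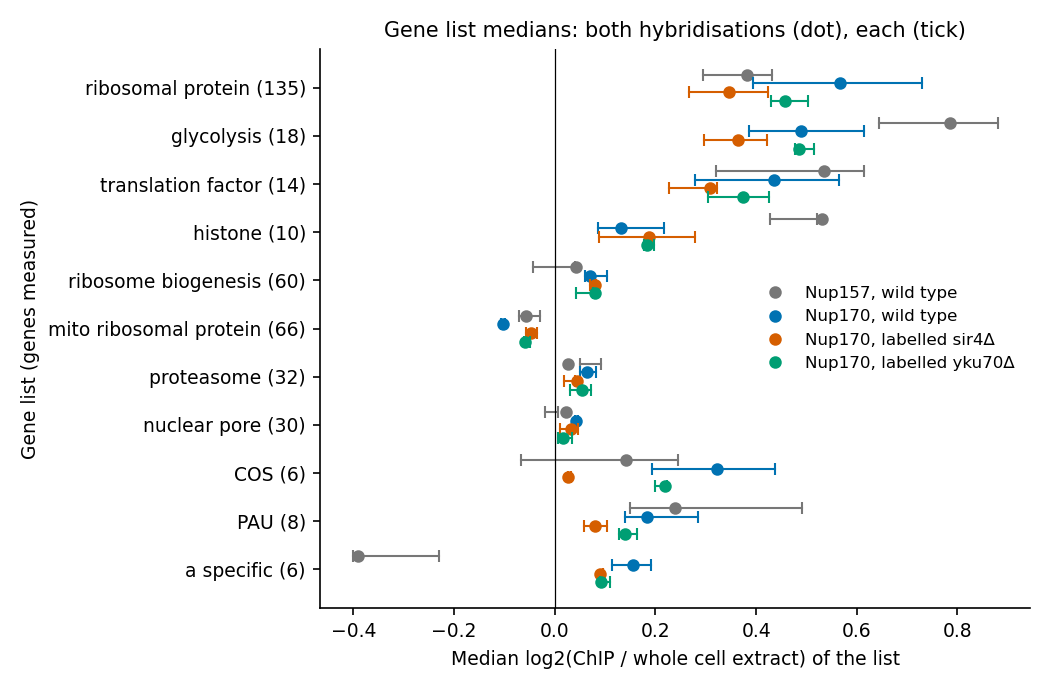
Median log2(ChIP / whole cell extract) of gene lists, with the number of genes measured, in the 4 libraries. Dots are the mean of both hybridisations and ticks each hybridisation; the ribosomal protein median of Nup170 in wild type is 0.57, with 0.73 and 0.39 in the single hybridisations.

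The whole cell extract channel, which reads the DNA of each strain, was used to ask whether the strains match their labels. In the library labelled sir4∆, all 15 probes inside SIR4 were lower than in the other libraries, with a median of -0.53 (-0.66 to -0.46), the lowest of 2755 genes with at least 5 probes. That left 69.3% (63.4% to 72.6%) of the signal, and 67.5% (62.8% to 70.2%) in the ChIP channel, whereas probes within 3000 bp either side had a median of 0.029. In the library labelled yku70∆, the 7 probes inside YKU70 were above blank spots with a median of -0.029 (-0.25 to 0.071), or 98.0% of the other libraries. For comparison, none of the 32 readings inside LEU2 and URA3, biosynthetic markers that the labels give as deleted in all 4 strains, was above blank. Of 2 HIS3 probes, 1 was above blank in each library. LYS2, which the labels also give as deleted in all, was at blank level at all 16 probes for Nup157 and above it at all 16 for each Nup170 library. Both deletion strains are therefore named by their labels below, and no direction in them can be tied to loss of SIR4 or YKU70 from these data alone.

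**Figure D2:**
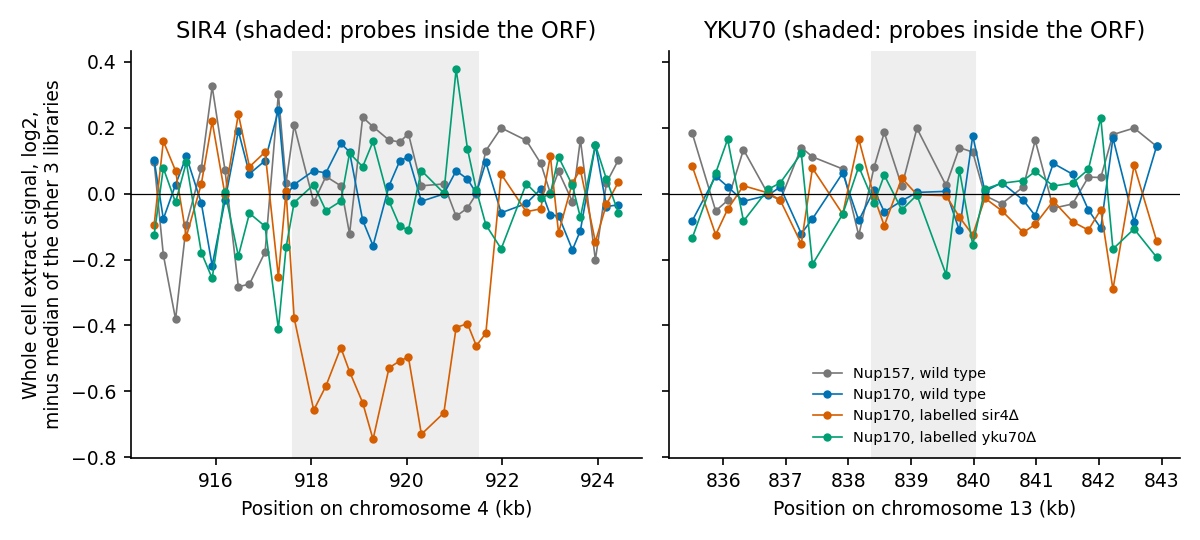
Whole cell extract signal (log2, minus the median of the other 3 libraries) of probes around SIR4 on chromosome 4 and YKU70 on chromosome 13, against position in kb. Lines are the 4 libraries and shading marks probes inside the ORF; the library labelled sir4∆ drops to a median of -0.53 inside SIR4, and the library labelled yku70∆ stays at -0.029 inside YKU70.

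Nup157 was compared with Nup170, both in strains labelled wild type, to see how far the 2 paralogs share sites. Without an untagged control, signal common to both Myc-tagged libraries cannot be told apart from shared binding sites. The Nup157 library also had high ratios over ribosomal protein and glycolytic genes, and its median at chromosome ends was lower. By the same filter, its highest genes included PMA1, the plasma membrane proton pump (YGL008C, chromosome 7, 480024 to 483035), at 1.25, ADH7 (YCR105W, chromosome 3, 308708 to 309842) at 1.22, PGK1, a glycolytic kinase, at 1.21, RPL3 at 1.19, HPF1, a cell wall glycoprotein, at 1.14, TDH3 at 1.12, ILV5, of branched-chain amino acid synthesis, at 1.12, ADH1 at 1.09 and OM14 at 1.08. Ribosomal protein genes had a median of 0.38 (0.33 to 0.43), with 129 of 135 above 0 and RPL36A at -0.42 and RPS27A at -0.36 lowest. All 18 glycolysis genes lay above 0 with a median of 0.79 (0.46 to 1.07), as did all 14 translation factor genes with 0.54 (0.10 to 0.85), and histone genes had 0.53 (0.37 to 0.68) with HHT1 at 0.75 and HHO1 at 0.68 highest and CSE4 at -0.13 lowest.

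Over the outermost 5 kb the Nup157 median was -0.035 (-0.15 to 0.052), and its difference from Nup170 was -0.38 (-0.46 to -0.32), below 0 in 29 of 32 arms. This difference kept its sign in all 4 pairings of the hybridisations, from -0.41 to -0.30. With an intensity trend removed, the Nup157 median there was 0.089 (0.0099 to 0.15) and the difference -0.25. Single ends were high with Nup157 too: 3 of its 15 regions with the highest maximum lay within 5 kb of an end, such as YHR218W with 3.23. The others, at YAR075W and YRF1-1, each held a probe near blank. Over 20 kb the Nup157 median was -0.10 (-0.13 to -0.055) and the difference -0.15 (-0.18 to -0.11), under each of the random runs. With the intensity trend removed these were -0.028 and -0.076, and with normexp the difference was -0.077. YFR057W differed by -1.09 and COS12 by -0.77. The a-specific genes, expressed in MATa cells only, had a median difference of -0.55 (-1.14 to 0.10), with STE2, for the alpha-factor receptor, at -1.14 and MFA1, for a-factor, at -0.67, while BAR1 was at -0.23 and ASG7 at 0.10. The Nup157 strain may be MATalpha, as described at the end, so strain and protein cannot be told apart at these genes. The remaining lowest genes were EMC4 at -1.14, SRT1 at -0.90, RPL28 at -0.83, CDC31 at -0.80, SLF1 at -0.79, MHF2, with 1 of 4 probes near blank, at -0.77, RPL36A at -0.77 and CSS3 at -0.75.

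Genes higher with Nup157 than with Nup170 included MRPL4 at 1.02 and MRPL8 at 0.91, for mitochondrial ribosomal proteins, PET122, an activator of mitochondrial translation, at 0.95, and AAC1, the mitochondrial ADP/ATP carrier, at 0.89. The others were YER039C-A at 1.04, NKP2, of the kinetochore, at 0.95, NHP6A, a chromatin protein, at 0.94, NAT4 at 0.90, ADO1 at 0.90 and NCP1 at 0.89. As a list, genes of mitochondrial ribosomal proteins differed by 0.053 (-0.029 to 0.19) with 38 of 66 above 0, inside the range of random lists, and MRP35 at -0.63 and MRPL25 at -0.55 were lowest. Inducible genes of the nuclear periphery differed by 0.25 (0.070 to 0.43), with 9 of 10 above 0, against -0.11 to 0.29 in random lists, from TSA2 at 0.43 and INO1 at 0.43 to GAL10 at 0.070 and GAL7 at -0.18. Glycolysis differed by 0.30 (0.039 to 0.42), but by -0.996 SDs once each library was divided by its lower-side SD, and by 0.53 in the second hybridisation and -0.00048 in the first. Histone genes differed by 0.34 (-0.054 to 0.57), with HHO1, for the linker histone, at 0.72 and HHF1 at 0.57 highest and HHT2 at -0.14 lowest.

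Of 135 probes enriched with Nup157, 128 were also enriched with Nup170, where independent sets gave 5.77. As far fewer probes passed with Nup157, these were 7.23% (6.07% to 8.54%) of the 1770 enriched with Nup170, against 0.326% for independent sets. Across 5567 genes, which are not independent replicates, Pearson's r between the libraries was 0.41, while that between the 2 hybridisations of Nup157 was 0.75. With a threshold of 1.08 (2.12-fold), against 0.41 for Nup170, only 28 regions were called for Nup157. A fixed threshold of 0.6 raised them to 538 and the share to 46.9%. When the top 5% of probes were taken in each library, the share was 27.3%. The ribosomal protein gene difference of -0.15 (-0.20 to -0.10) was -0.37 in the first hybridisations and 0.068 in the second, so it did not exceed the spread between hybridisations.

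Nup170 in the strain labelled sir4∆ was compared with Nup170 in wild type, to ask whether Nup170p binding depends on silencing factors. The profile kept its main features: 65.8% (63.5% to 68.0%) of the probes enriched in wild type were enriched here too, against 3.33% for independent sets, and r across genes was 0.85. Single hybridisations of the 2 libraries gave r of 0.73 to 0.77. Within a library r was 0.79 for Nup170 in wild type and 0.72 here, so the whole profiles differed little more than repeat hybridisations. The signal at chromosome ends was lower. Over the outermost 5 kb the median was 0.083 (0.059 to 0.12), and the difference from wild type was -0.16 (-0.19 to -0.13), below 0 in 31 of 32 arms and between -0.22 and -0.14 in the 4 pairings of hybridisations. YFR057W, next to the end of chromosome 6, differed by -0.55 and COS12 (YGL263W, chromosome 7, 2429 to 3758, with 1 of 7 probes near blank) by -0.54, the lowest 2 genes. All 6 measured COS genes lay below 0 with a median of -0.21 (-0.54 to -0.018), and 7 of 8 PAU genes, with a median of -0.16 (-0.35 to 0.11) and PAU10 at -0.35 and PAU19 at -0.31 lowest. Their members match each other closely, so a probe may read several of them.

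Further inward the difference was smaller. Over 20 kb it was -0.027 (-0.042 to -0.012), or -0.081 (-0.095 to -0.063) with normexp background correction, and without the outermost 5 kb it was -0.0017. HMRA1, the only measured gene of the silent mating loci, differed by -0.0086. Its sequence also lies at MAT in MATa cells, so that value may mix both loci. The 19 probes within 3000 bp on either side of HMRA1, looked at after seeing the data, had medians of 0.21 here and 0.46 in wild type. Their difference was -0.26 (-0.57 to 0.11), with 13 below 0. The same probes were also lower than in wild type in the library labelled yku70∆, by -0.17 (-0.40 to -0.023) with 15 below 0, and with Nup157, by -0.87 (-1.44 to -0.64) with 18 below 0. Silencing factor genes differed by 0.0067 (-0.035 to 0.061) and nuclear pore genes by -0.010 (-0.041 to 0.014). With normexp the outermost median in this library turned to -0.056, while the difference from wild type was -0.22. The doubt about the SIR4 label applies to each of these directions.

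**Figure D3:**
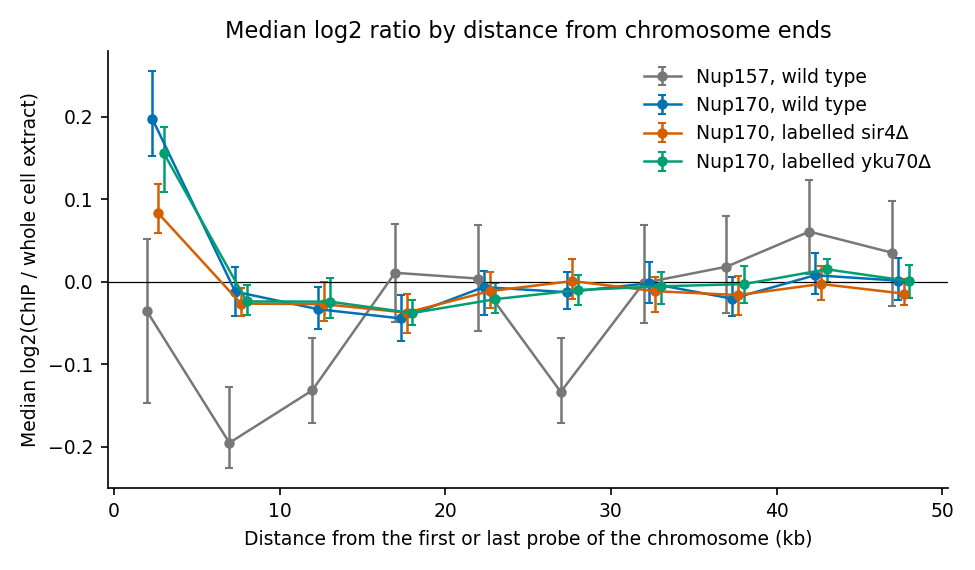
Median log2(ChIP / whole cell extract) in steps of 5 kb from the first or last probe of each chromosome, in the 4 libraries. Points are medians with 95% intervals over probes; in the outermost 5 kb they are 0.20 for Nup170 in wild type, 0.16 for the library labelled yku70∆, 0.083 for the library labelled sir4∆ and -0.035 for Nup157.

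Ribosomal protein genes were also lower in the library labelled sir4∆ when hybridisations were averaged, with a median of 0.35 (0.31 to 0.39), a difference of -0.22 (-0.24 to -0.21) and 129 of 135 below 0. RPL13B differed by -0.50, RPL37A by -0.50, RPL2B by -0.42, RPL39 by -0.38, RPS19B by -0.38, RPL28 by -0.36 and RPS4A by -0.36, and RPP2B at 0.12 and RPL15B at 0.074 were highest. TEF2 and TEF1 differed by -0.49 and -0.51, translation factors as a list by -0.10 (-0.24 to -0.036), and glycolysis by -0.11 (-0.19 to -0.028) with FBA1 at -0.25 and ADH1 at -0.25 lowest. These differences did not exceed the spread between hybridisations: with the second hybridisation alone they were 0.029 for ribosomal protein, 0.054 for translation factor and 0.088 for glycolysis genes. The strain doubt holds for them as well.

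The highest genes in the library labelled sir4∆, by the same filter and apart from SRD1, whose ratio cannot be read with 3 of 4 probes near blank, were MUD1 at 1.03 and TIM9 at 1.02, each with 1 probe near blank and TIM9 beside the deleted URA3, then ADH7 at 1.01, RPL7A at 0.89, RPL8A at 0.87, RPS14B at 0.76, YDR524W-A at 0.75 with 1 probe near blank, GCN4, the activator of amino acid synthesis genes, at 0.74 and RPL28 at 0.70. Highest in the difference was DSF1 at 0.89, with 1 of 3 probes near blank; its hybridisations gave 2.08 and 0.71 here and -0.39 and 1.41 in wild type. The others were ATG10, an autophagy enzyme gene, at 0.45, YAE1 at 0.41, MCO10 at 0.35, AGX1 at 0.33, KNH1 at 0.31, CUE4 at 0.31, MVB12 at 0.30, MHR1 at 0.30 and ARG3, of arginine synthesis, at 0.30. Mitochondrial ribosomal protein genes differed by 0.044 (0.021 to 0.074), with MRP2 at 0.23 highest. At a threshold of 0.35, 310 enriched regions were called, of which 18 lay within 5 kb of an end. With a fixed threshold of 0.6 the regions numbered 94 and the shared probes were 40.5%.

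Nup170 in the strain labelled yku70∆ was compared with wild type in the same way. Its profile was the closest of the 3, with 88.8% (87.2% to 90.2%) of the wild-type enriched probes also enriched, against 4.84% for independent sets, and r across genes of 0.91. The outermost 5 kb had a median of 0.16 (0.11 to 0.19), with a difference of -0.068 (-0.090 to -0.053) that was below 0 in 29 of 32 arms and between -0.12 and -0.035 in the pairings of hybridisations. With normexp the median there was 0.060, against 0.14 in wild type. YFR057W was the lowest gene that passed the filter, at -0.35. Over 20 kb the difference was -0.0073 (-0.019 to 0.0039). COS genes differed by -0.12 (-0.22 to 0.0014), led by COS12 at -0.22, PAU genes by -0.066 (-0.18 to 0.054), and FLO genes, for cell surface adhesins, by 0.076 with all 5 above 0 and FLO9 at 0.19 highest.

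Ribosomal protein genes in this library had a median of 0.46 (0.41 to 0.51) and a difference of -0.10 (-0.12 to -0.088), which became 0.023 with the second hybridisation alone. Low members included RPS16A at -0.29, RPL23A at -0.25, RPS4A at -0.25, RPL6A, with 1 of 5 probes near blank, at -0.24 and RPL27B at -0.22, and RPP2B at 0.16 was highest. Other low genes were ECM12 at -0.25, HUG1, of the DNA damage response, at -0.23 and DFP2 at -0.22. Highest were YAE1 at 0.44, CTF8 at 0.31, YPT6, for a Rab GTPase, at 0.30, INH1 at 0.30, AGX1 at 0.29, MHF1 at 0.27, EMC6 at 0.27, AQY1, for an aquaporin, at 0.26, RTG1 at 0.26 and HUA1 at 0.25. In the library itself, the highest genes that passed the filter were ADH7 at 1.21, TDH3 at 1.13, RPL7A at 1.06, RPL8A at 1.02, RPS14B at 0.89, RPL2B at 0.86, RPL28 at 0.86, GCN4 at 0.82, GLY1 at 0.80 and RPL30 at 0.79. At a threshold of 0.33, 411 enriched regions were called. Of these, 24 lay within 5 kb of an end, against 22 in wild type at a threshold of 0.41. With a fixed threshold of 0.6 the regions numbered 152 and the shared probes were 66.7%, and at 2 SDs there were 755 regions. As YKU70 DNA was at 98.0% of the other libraries, none of these directions can be read as an effect of its loss.

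**Figure D4:**
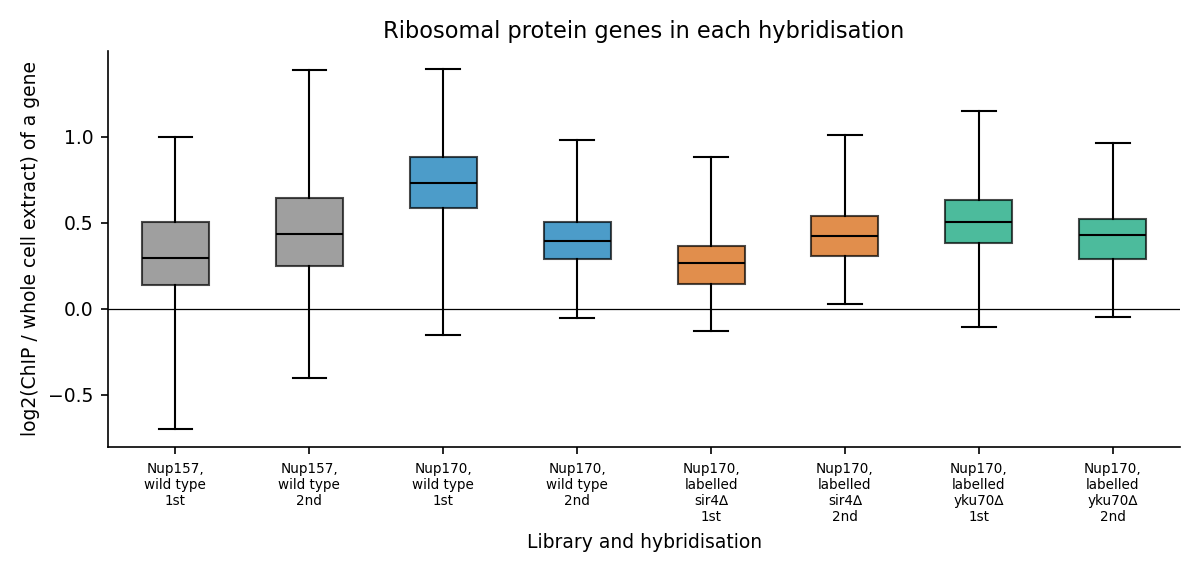
Log2(ChIP / whole cell extract) of the 135 ribosomal protein genes in each hybridisation of the 4 libraries. Boxes span the quartiles with the median as a line and whiskers reach the lowest and highest gene; medians of Nup170 in wild type are 0.73 and 0.39, and those of the library labelled sir4∆ 0.27 and 0.42.

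Lists with medians nearer to 0 are given once for all 4 libraries, in the order Nup157, Nup170 in wild type, labelled sir4∆ and labelled yku70∆. Proteasome genes had 0.027, 0.063, 0.044 and 0.054 over 32 genes, led by RPN10 at 0.93 with Nup157 and by PRE2 at 0.28 in the library labelled yku70∆. Nuclear pore genes had 0.023, 0.043, 0.033 and 0.016 over 30 genes, with SEC13 at 0.48 with Nup157 and NUP120 at 0.20 with Nup170 in wild type. Silencing factor genes had -0.14, -0.037, -0.0067 and -0.033 over 13 genes, with RAP1 at 0.16 and SIR3 at -0.17 with Nup170 in wild type. Haploid-specific genes had -0.11, -0.017, -0.018 and -0.046 over 9 genes, with STE5 at -0.54 with Nup157. Genes of amino acid biosynthesis had 0.27, 0.058, 0.018 and 0.038 over 30 genes, with ILV5 at 1.12 and HIS5 at -0.58 with Nup157. FLO genes had 0.17, 0.061, 0.11 and 0.14 over 5 genes. HMRA1 stood at -0.18, 0.34, 0.34 and 0.29. Inducible genes of the nuclear periphery had 0.23, -0.030, -0.045 and -0.041 over 10 genes, with INO1 at 0.51 with Nup157 and GAL7 at -0.32 with Nup170 in wild type. Of these lists, proteasome and nuclear pore genes turned to -0.10 and -0.063 for Nup170 in wild type when upstream probes alone were used. So did nuclear pore genes in the library labelled sir4∆, to -0.026, and amino acid biosynthesis genes in the library labelled yku70∆, to -0.13, the latter also turning to -0.012 with the intensity trend removed.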

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

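The tests in this part were chosen only after the result was seen, except that leaving out probes near the blank level was written down before it, and division by the lower-side SD was a setting fixed in advance that was read as a test only afterwards. Single channels held signal at several genes that the labels give as deleted. As the mean of both hybridisations, the ChIP channel read URA3 at 11079 units for Nup170 in wild type, 7265 in the library labelled sir4∆ and 13885 in the library labelled yku70∆, with 4 of 4 probes above blank spots in each. The hybridisations differed widely, with 23106 and 4664 in the last, so the order of the libraries is not fixed. LEU2 was above blank in that channel at 3 of 4 probes for Nup170 in wild type and 1 of 4 in the library labelled yku70∆, while both genes were at blank level in the whole cell extract of the same strains. The whole cell extract signal of LYS2 was 98.8%, 104% and 101% of that in the other libraries with signal, at most probes the other Nup170 libraries alone, for Nup170 in wild type, labelled sir4∆ and labelled yku70∆. That of SIR4 was 69.3% in the library labelled sir4∆, and that of YKU70 was 98.0% in the library labelled yku70∆.

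SIR4 DNA was present at a reduced level in the library labelled sir4∆, with all 15 probes lowered and the flanks at 0.029. Probes that read signal from elsewhere are argued against by LEU2 and URA3, where 0 of 32 readings in the whole cell extract were above blank. An exchange with the library labelled yku70∆ is argued against by YKU70, which stood at -0.011 (-0.13 to 0.047) in the library labelled sir4∆. A mixture of cells with and without SIR4 may account for it: 69.3% was left in the whole cell extract and 67.5% in the ChIP channel, over the whole gene. Where the SIR4 DNA came from stays open, and MET17 at blank level in this library leaves little room for DNA of the Nup157 strain, in which MET17 was present.

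Nup170 ratios in the outermost 5 kb of chromosomes were lower in the library labelled sir4∆ than in wild type, by a median of -0.16. A narrower background spread is argued against, since the difference was -0.64 SDs (-0.81 to -0.49) after division by each library's lower-side SD. That SD is taken from background, so the division cannot test weaker enrichment as a whole. Gaps without an RNA gene were nearer to 0 here (-0.053 against -0.12), while gaps with a tRNA gene had 0.16 in both libraries. Without probes near the blank level the difference at chromosome ends was again -0.16 (-0.19 to -0.13). Weak probes thus do not account for the difference. In the 4 pairings of hybridisations the highest value was -0.14 and the lowest -0.22. As each library holds only 2 hybridisations, the pairings cannot exclude the spread between hybridisations. Less Nup170p at chromosome ends in cells without SIR4 could give the same pattern and stays open as untested. With 1 library and SIR4 DNA still at 69.3%, a difference between cultures or ChIP reactions cannot be set apart from it by any value here. Nup157 and the library labelled yku70∆ were also lower there than Nup170 in wild type, by -0.38 and -0.068. All these differences subtract the same wild-type library, so they are not independent of each other.

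Ribosomal protein genes were lower in the library labelled sir4∆ than in wild type when hybridisations were averaged, by a median of -0.22. The spread between hybridisations may account for it, since the 4 pairings ran from -0.46 to 0.029. A narrower background spread as the whole cause is argued against, as the difference was -0.73 SDs (-0.85 to -0.62) after division by the lower-side SD. Weaker enrichment as a whole cannot be tested by that division. A biological difference stays open as untested.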

How the results depend on the processing

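The settings that use 1 hybridisation or count left ends from coordinate 1, and all values of the outermost 5 kb, were chosen only after the result was seen. Over the settings that keep the log2 scale, the difference in the outermost 5 kb kept its direction in all 11, from -0.44 to -0.23 for Nup157, from -0.22 to -0.13 for the library labelled sir4∆ and from -0.11 to -0.056 for the library labelled yku70∆. Ribosomal protein gene medians stayed above 0 in all 13, from 0.27 to 0.95 for Nup157, from 0.39 to 1.02 for Nup170 in wild type, from 0.21 to 0.67 and from 0.34 to 0.83 in the libraries labelled sir4∆ and yku70∆. No value changed without centring, with spots marked for exclusion kept, without probes near blank or within 30 kb by more than its 95% interval, or 1.5 times for counts. Over all settings, 292 values of the main results stayed within those bounds, 121 moved beyond them and 6 reversed, and among other values, of gene lists, 1439 stayed, 224 moved and 26 reversed. Every change among the main results and every reversal follows by setting, and the cause was not tested. Values are log2, counts of regions, or percent of Nup170 wild-type enriched probes also enriched in the library named. Libraries are called Nup157, Nup170, sir4∆ and yku70∆ (the latter 2 as labelled), and differences are from Nup170.

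Normexp gave Nup157 188 regions, and ribosomal protein gene medians of 0.62, 1.02, 0.67 and 0.83 for Nup157, Nup170, sir4∆ and yku70∆. Subtelomere medians became -0.039 for Nup170, -0.094 for sir4∆ and -0.050 for yku70∆, and those of the outermost 5 kb 0.14, -0.056 (reversed) and 0.060. Subtelomere differences were -0.077 for Nup157 and -0.081 for sir4∆, outermost ones -0.23 and -0.22, and those of ribosomal protein genes -0.34 for Nup157, -0.33 for sir4∆ and -0.14 for yku70∆. Shares were 17.1%, 53.2% and 81.4% for Nup157, sir4∆ and yku70∆. Reversed were mitochondrial ribosomal protein genes in sir4∆, at 0.013, and the meiosis difference of sir4∆, at -0.0085.

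The authors' combined ratio moved sir4∆ alone, with a ribosomal protein gene median of 0.27, a difference of -0.30 and a share of 50.3%. Centring on the mode moved the subtelomere median of yku70∆ to 0.0062. Division by the lower-side SD took the ribosomal protein gene difference of yku70∆ to -0.038 SDs, with an interval reaching 0, and reversed the glycolysis difference of Nup157, at -0.996 SDs. Without COS, PAU and YRF1 probes the outermost medians were 0.14 for Nup170 and 0.11 for yku70∆.

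Removal of an intensity trend gave Nup157 54 regions, a share of 12.3%, a subtelomere median of -0.028, an outermost median of 0.089, and differences of -0.076 and -0.25 there. Subtelomere medians were 0.019 for Nup170 and 0.010 for yku70∆. Ribosomal protein gene medians were 0.27, 0.48, 0.31 and 0.38 in library order, with differences of -0.21 for Nup157 and -0.19 for sir4∆. Amino acid biosynthesis genes in yku70∆ reversed to -0.012.

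At 2 SDs the libraries had 256, 661, 628 and 755 regions, with shares of 15.5% for Nup157 and 84.2% for yku70∆. At 4 SDs they had 11, 222, 178 and 266, with shares of 4.34% and 91.2%. A fixed 0.6 gave 538, 198, 94 and 152 regions and shares of 46.9%, 40.5% and 66.7% for Nup157, sir4∆ and yku70∆. The top 5% of probes gave Nup157 466 regions and shares of 27.3%, 75.4% and 83.3%. No smoothing gave 18, 194, 135 and 238 regions, with shares of 10.3% for Nup157 and 84.9% for yku70∆. Smoothing over 1000 bp gave sir4∆ a share of 68.9%, and regions of at least 3 probes numbered 16 for Nup157.

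Within 10 kb, subtelomere medians were -0.14, 0.062, 0.016 (reversed) and 0.036, and differences -0.25, -0.066 and -0.036. Without the outermost 5 kb, medians were -0.030, -0.030 and -0.028 in the Nup170 libraries, and differences -0.10, -0.0017 and 0.010. With left ends from coordinate 1, the Nup157 median was -0.13 and its difference -0.18.

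ORF probes alone gave ribosomal protein gene medians of 0.45 for sir4∆ and 0.54 for yku70∆, and a difference of -0.18 for sir4∆. Upstream probes alone gave medians of 0.32, 0.47, 0.21 and 0.34, and differences of -0.26 for sir4∆ and -0.13 for yku70∆. They reversed ribosome biogenesis, at -0.14, -0.065 and -0.079, and glycolysis, at -0.31, -0.015 and -0.20, in Nup170, sir4∆ and yku70∆. They also reversed the glycolysis difference of sir4∆ (0.14), proteasome genes in Nup170 (-0.10), nuclear pore genes in Nup170 (-0.063) and sir4∆ (-0.026), the nuclear pore difference of yku70∆ (0.0080) and amino acid biosynthesis in yku70∆ (-0.13). The highest probe of a gene gave ribosomal protein gene medians of 0.95, 0.90, 0.64 and 0.75 and differences of 0.033 (reversed), -0.25 and -0.12. It reversed mitochondrial ribosomal protein genes, at 0.11, 0.13 and 0.13 in Nup170, sir4∆ and yku70∆, and meiosis genes, at 0.37, 0.17 and 0.12 in Nup157, Nup170 and yku70∆, since a maximum lies above a mean by construction.

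The first hybridisation alone gave ribosomal protein gene medians of 0.29, 0.73 and 0.27 for Nup157, Nup170 and sir4∆, and differences of -0.37, -0.46 and -0.21. It gave outermost differences of -0.22 for sir4∆ and -0.11 for yku70∆, a subtelomere median of 0.0047 for yku70∆ and shares of 4.59%, 51.0% and 86.5%. It reversed the glycolysis difference of Nup157, at -0.00048. The second alone gave ribosomal protein gene medians of 0.43, 0.39 and 0.42, and reversed all 3 differences, at 0.068, 0.029 and 0.023. It gave a subtelomere median of 0.018 for Nup170, an outermost difference of -0.30 for Nup157 and shares of 10.6%, 72.9% and 79.9%. For sir4∆ it reversed the differences of glycolysis (0.088), translation factors (0.054) and meiosis (-0.019).

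No paired analysis was possible because each group holds 1 library. Leaving out a replicate was not run for the same reason, and the correction for GC content was not run because probe sequences were not used here. Few probes, 157 to 182 of 41480, were near blank in the whole cell extract, but many fell in the highest regions. Of the 15 regions with the highest maximum, 4, 3, 8 and 7 held such a probe in Nup157, Nup170, sir4∆ and yku70∆. Background treatment mattered as well: with normexp, 20 of the main values moved, 1 reversed and 7 stayed. The spread of Nup157 ratios hid most simulated regions of 0.5.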

Other observations

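The gaps that hold RNA genes, the comparison by probe position and the test on the flanks of HMRA1 were chosen only after the result was seen; the test on alpha-specific genes was set before its result was seen. Nup170p signal was also high around genes for small RNAs. Outside the outermost 20 kb, probes in gaps between protein genes that hold a tRNA gene had a median log2 ratio of 0.16 (0.12 to 0.19) over 237 gaps with Nup170 in wild type, 0.16 (0.14 to 0.20) in the library labelled sir4∆ and 0.13 (0.11 to 0.17) in the library labelled yku70∆, and 194, 202 and 201 of the gaps lay above 0. With Nup157 the same gaps had -0.033 (-0.087 to 0.027), a difference of -0.23 (-0.26 to -0.15) from Nup170. Gaps with snoRNA genes, whose products guide the modification of ribosomal RNA, had 0.43 (0.20 to 0.49) over 47 gaps with Nup170 in wild type, 0.27 (0.17 to 0.38) and 0.36 (0.21 to 0.45) in the libraries labelled sir4∆ and yku70∆, and 0.056 (-0.036 to 0.16) with Nup157. Their difference from wild type was -0.12 (-0.16 to -0.069) in the library labelled sir4∆ and -0.044 (-0.070 to -0.018) in the library labelled yku70∆, while tRNA gaps differed by -0.0041 and -0.0053. Gap values were not split by hybridisation, so whether these differences exceed the spread between hybridisations was not tested. Gaps without an RNA gene had medians below 0 in all 4 libraries, at -0.082, -0.12, -0.053 and -0.091 for Nup157, Nup170 in wild type, labelled sir4∆ and labelled yku70∆.

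Downstream of genes, Nup170 medians were also above 0. Chromosome ends and gaps with RNA genes were not left out of these probes, so a separate downstream signal was not tested. Probes that the files place downstream had medians of 0.10 (0.086 to 0.13), 0.12 (0.10 to 0.13) and 0.074 (0.058 to 0.086) in the Nup170 libraries labelled wild type, sir4∆ and yku70∆, but -0.17 (-0.20 to -0.13) with Nup157, and the difference of Nup157 from Nup170 was -0.31 (-0.34 to -0.29) over 1617 probes. Probes at promoters had -0.10 with Nup157 and -0.087, -0.038 and -0.070 with Nup170 in the same order, those between divergent genes -0.036, -0.13, -0.076 and -0.094, and those inside genes 0.030, 0.020, 0.010 and 0.016. The authors' own marks place 2145 probes in bound regions for Nup157, 2233 for Nup170 in wild type, 1958 in the library labelled sir4∆ and 2216 in the library labelled yku70∆. Of those for Nup170 in wild type, 558, 1383 and 1798 were also marked for Nup157, labelled sir4∆ and labelled yku70∆, or 24.99%, 61.9% and 80.5%, against 5.17%, 4.72% and 5.34% for independent sets.

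The Nup157 strain differed in its DNA from the Nup170 strains at several loci. MET17, of methionine synthesis, was above blank at 3 of 3 probes for Nup157 and at 0 of 3 in each Nup170 library, the reverse of LYS2. HMRA1, whose sequence lies at HMR and, in MATa cells, also at MAT, was lower for Nup157 in the whole cell extract, at -0.83 on 2 probes. This whole set is that of a MATalpha, lys2 strain against MATa, met17 strains, although the labels give MATa and lys2∆ for all, so a candidate explanation is that the Nup157 library comes from MATalpha cells. A lower signal of the region as a whole is argued against by the flanks of HMRA1, at 0.23 (0.14 to 0.28). The test on binding left the hypothesis open, as binding ratios do not read the mating type locus itself. The 4 alpha-specific genes MF(ALPHA)1, MF(ALPHA)2, STE3 and SAG1 had a median difference from Nup170 of 0.043, with a range of -0.17 to 0.28, while the 6 a-specific genes had -0.55. Comparisons of Nup157 with Nup170 therefore carry a difference in strain as well as in protein.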
